A study of Mus musculus with 11 samples.

How the data were processed

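Polyadenylated RNA from 11 libraries of E14 mouse embryonic stem cells at day 0 and during differentiation with RA and SAG was measured by sequencing, with 2 libraries at each of days 0, 1, 2 and 3 and 3 Prominin-1 sorted libraries called day 3.5. Per the labels, RNA was extracted with a ZymoPure kit and libraries were made with Illumina TruSeq polyA selection. Tools named without roles in the submitters' processing notes are bcl2fastq 1.8.3, CASAVA, TopHat2 2.0.4, HTSeq 0.6.1, Cufflinks 2.1.1 and limma, with builds GRCm38 and mm10. The annotation and the counting strand are not given in the sources used here, so overlapping and antisense genes and near-identical copies remain uncertain.

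The deposited count table holds 38197 genes by symbol in 11 columns, of which 38093 genes have whole counts and 104 have fractions, so the values were taken to be expected counts and rounded. How the fractional values arose is not given in the sources used here. The deposited log2 (voom) values equal the log2 CPM of the count plus 0.5 over the library total plus 1, with a largest difference of 4.97e-14 when recomputed from the counts. The deposited FPKM values were made by the authors, with Cufflinks among the tools in the submitters' processing notes. All columns were matched to libraries through the labels' descriptions, with 0 unmatched. Library totals ran from 13173674 to 30384599 counts. A level below 3 counts in a library was treated as at the floor, which covers counting error only.

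Counts were tested in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood F test after TMM scaling and filterByExpr with a minimum count of 10, and p-values were Benjamini-Hochberg adjusted with a threshold of 0.05 over all genes tested. Days 0 to 3 were fitted on their 8 libraries (16810 genes) in a group means model, which gave day 1 against 0, day 2 against 1, day 3 against 2, day 3 against 0 and the F test of any change. Day 3.5 against day 3 was fitted on all 11 libraries (17006 genes). CPM levels used TMM factors over all 11 libraries. The replicate numbers were not used as a block. The SE of a log2 fold change was taken as its size over the square root of F.

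A set of 29 gene lists was written before the data were examined. They are naive pluripotency, general pluripotency, formative epiblast, neural progenitor, retinoic acid response, Hox paralog groups 1 to 4 and 5 to 13, hindbrain regionalization, forebrain and midbrain, hedgehog targets, hedgehog receptors and mediators, ventral progenitor, and dorsal and intermediate progenitor. The others are neuronal differentiation, Notch pathway, mesoderm and definitive endoderm, extraembryonic endoderm, trophoblast and surface ectoderm, neural crest, fibroblast, 2-cell-like, FGF/ERK targets, Wnt, Nodal and BMP targets, DNA methylation and demethylation, S phase, G2 and M phase, immediate early and dissociation stress, p53 and apoptosis, and glycolysis and hypoxia. Hoxd4, Tubb3, Foxc2, Zscan4a and Gins2 were not analysed here. Each list was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 29 lists within a comparison. Hox order was tested by Spearman's rho with 100000 permutations.

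Genes were named by a rule with 3 parts. These were the 6 largest changes in each direction among called genes with at least 5 CPM in the higher group and no overlap between libraries, a fixed panel, and up to 4 called members of each list with the smallest adjusted p. Symbols that are only clone, predicted-gene or locus numbers were left out of the largest changes. Gene positions came from GENCODE M21 on GRCm38, matched by symbol, and 92.7% of tested genes had a GC content this way. No fold is given for a gene with 3 or fewer counts in a group.

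Other settings chosen before the data were examined were RLE size factors, no filter on low counts, DESeq2 1.42.0, other libraries in the fit, the replicate number as a block, a minimum absolute log2 fold change of 1, deposited FPKM with pseudocount 1 or 0.1 and an FPKM of at least 1 in 2 or more libraries, FPKM without that filter, the deposited voom values with limma, and leaving out each library in turn. Settings added after seeing the data were a GC offset from lowess with span 0.3 on the GC content of the longest transcript, and leaving out the 3 libraries with the lowest or with the highest GC trend.

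The tests were run on simulated data with 200 genes changed and each gene drawn independently with its own dispersion. The simulated replicates had no shared trend along GC content, unlike the real ones of days 0 and 1. The rates below therefore need not hold for the real data. In the simulated day 1 against day 0, over 16433 genes, edgeR recovered 23.71% of 2-fold and 76.53% of 4-fold changes with 5 false calls. In the simulated day 3.5 against day 3, over 16514 genes, it recovered 37.5% and 81.63% with 8 false calls. DESeq2 made 26 and 36 false calls on the same data. Figures were drawn with matplotlib 3.10.9. Raw reads were not used here.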

Results

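Polyadenylated RNA was sequenced from E14 cells, a mouse embryonic stem cell line, at day 0, where the titles call them stem cells, and during differentiation in monolayer toward ventral hindbrain neurons. Differentiating cells received retinoic acid (RA), which patterns the hindbrain, and SAG, an agonist of Smoothened that switches on hedgehog signaling. Unsorted cultures were sampled at days 0, 1, 2 and 3 with 2 libraries each, and 3 further libraries held cells sorted for Prominin-1, a surface protein of neural progenitors. The sorted libraries are called day 3.5 here after their cell status, although another of their labels says 3 days. Total counts were 30384599 and 26136331 at day 0, 27969547 and 30097311 at day 1, 26926642 and 27074094 at day 2, and 30115258 and 30264387 at day 3. The day 3.5 libraries held 17113430, 15486744 and 13173674. Levels are means of TMM-scaled CPM ± SD, with n = 2, or n = 3 at day 3.5. Log2 fold changes are from edgeR, with their SE and Benjamini-Hochberg adjusted p. The labels do not say whether libraries of a day came from separate cultures, so each p-value measures the spread between these samples. That spread was estimated per gene over all libraries of a fit, not only from the groups compared. The 29 gene lists, their tests and the rule for naming genes were chosen before the data were examined. The GC settings, the naming of Stra8 at day 1 and the lists of germ cell and neuron subtype genes were chosen afterwards.

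Days were the main axis of the data. The leading principal component held 73.3% of the variance of 13810 genes and the next component 10.1%. Of 16810 genes tested across days 0 to 3, 9033 changed on at least 1 day by the edgeR F test. Of these, 3336 had their highest mean log2 CPM on day 0, 1512 on day 1, 723 on day 2 and 3462 on day 3. Log2 differences between replicate libraries had an SD of 0.45 at day 0 and 0.465 at day 1, against 0.192 at day 2 and 0.317 at day 3. The tests pooled the spread over days, so a comparison was not judged by the spread of its own days alone.

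**Figure D1:**
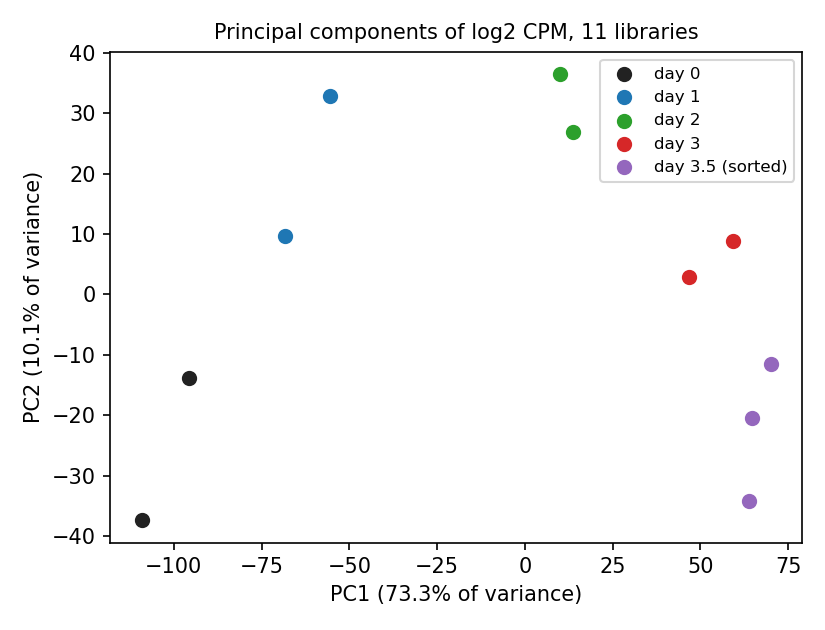
Each point is 1 library, placed by its scores on the leading pair of principal components of log2 CPM, which hold 73.3% and 10.1% of the variance. Colors give the day, and the 3 sorted libraries lie beside the day 3 libraries on the horizontal axis.

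Which genes answered the switch to differentiation conditions on the opening day was asked by comparing day 1 with day 0. Transcription factors of naive pluripotency fell within a day. Nanog (GRCm38 chromosome 6, 122707489 to 122714633) fell from 221 ± 57.9 to 7.35 ± 1.03 CPM (log2 fold change -4.91 ± 0.31, adjusted p = 7.47e-05), and Esrrb fell from 184 ± 59.8 to 13.6 ± 3.62 CPM. Pou5f1, the general pluripotency factor, still stood at 82 ± 37.8 CPM after 435 ± 145 at day 0, a fall whose adjusted p was 0.00248 by edgeR and 0.0553 with log2(FPKM + 1) without a filter. At the same time the enzymes that degrade RA and the RA receptor beta were switched on. Cyp26a1 (chromosome 19, 37697798 to 37701536) rose from 6 ± 0.413 to 219 ± 22.5 CPM (log2 fold change 5.19 ± 0.31, adjusted p = 6.73e-05), and Rarb rose from 2.85 ± 0.625 to 82.5 ± 3.18 CPM. The RA-inducible meiosis gene Stra8, singled out after its values were seen, reached 1377 ± 84.4 CPM from 74.3 ± 23. Of the genes tested, 2015 were higher and 1498 lower at day 1.

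The naive pluripotency list had 0 of 15 tested genes higher, 15 lower and 0 not called (0 and 15 adjusted over the list alone, camera adjusted p = 1.67e-14, and adjusted p = 0.196 with an estimated correlation). General pluripotency genes had 0 of 12 tested genes higher, 10 lower and 2 not called (0 and 10 adjusted over the list alone, camera adjusted p = 5.25e-08, and adjusted p = 0.0942 with an estimated correlation). The formative epiblast list, genes of the state that follows the naive one, had 1 of 12 tested genes higher, 6 lower and 5 not called (1 and 6 adjusted over the list alone), and Dnmt3b, a DNA methyltransferase, fell from 622 ± 134 to 176 ± 7.17 CPM. Targets of FGF/ERK signaling, which drives exit from pluripotency, had 0 of 12 tested genes higher, 7 lower and 5 not called (0 and 8 adjusted over the list alone, camera adjusted p = 1.44e-06, and adjusted p = 0.0942 with an estimated correlation). Among them Spry4, an inhibitor of the pathway, fell from 154 ± 1.79 to 19.5 ± 3.35 CPM. The Wnt, Nodal and BMP targets had 1 of 14 tested genes higher, 8 lower and 5 not called (1 and 10 adjusted over the list alone, camera adjusted p = 4.29e-06, and adjusted p = 0.196 with an estimated correlation). Lefty1 and Lefty2, the secreted Nodal antagonists, fell to 0.748 ± 0.218 and 0.364 ± 0.25 CPM from 93 ± 4.03 and 141 ± 20.7. Tdgf1, the Nodal co-receptor, fell from 459 ± 58 to 2.53 ± 0.753 CPM, and whether reads were shared with the pseudogene Tdgf1-ps1 was not tested, so its own level is uncertain. Id1, a BMP target, fell from 16.2 ± 0.93 to 0.882 ± 0.432 CPM. Ldha, lactate dehydrogenase, fell (log2 fold change -2.52 ± 0.27), within a glycolysis and hypoxia list of 2 of 16 tested genes higher, 7 lower and 7 not called (2 and 10 adjusted over the list alone).

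The RA response list had 14 of 17 tested genes higher, 0 lower and 3 not called (14 and 0 adjusted over the list alone, camera adjusted p = 6.86e-13, and adjusted p = 0.161 with an estimated correlation). Hox genes of paralog groups 1 to 4 had 11 of 11 tested genes higher, 0 lower and 0 not called (11 and 0 adjusted over the list alone, camera adjusted p = 3.38e-09, and adjusted p = 0.196 with an estimated correlation). Hoxb1 (chromosome 11, 96365752 to 96368256) rose from 3.64 ± 0.667 to 51.7 ± 1.46 CPM. Hoxb4 reached 13.6 ± 2.91 CPM. Groups 5 to 13 had 9 of 19 tested genes higher, 0 lower and 10 not called (9 and 3 adjusted over the list alone, camera adjusted p = 0.00345, and adjusted p = 0.466 with an estimated correlation). Hedgehog targets had 4 of 8 tested genes higher, 0 lower and 4 not called (4 and 0 adjusted over the list alone, camera adjusted p = 0.0205, and adjusted p = 0.386 with an estimated correlation). The pathway's receptors and mediators had 5 of 10 tested genes higher, 0 lower and 5 not called (6 and 0 adjusted over the list alone, camera adjusted p = 0.00216, and adjusted p = 0.218 with an estimated correlation). Ptch1, the hedgehog receptor and feedback target, rose from 27.2 ± 1.58 to 88.8 ± 20.9 CPM, and Hhip, a hedgehog-binding inhibitor, from 0.491 ± 0.214 to 8.15 ± 1.49 CPM.

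Of the day 1 calls, 57.36% were higher by edgeR, 71.8% with the deposited voom values and 71.3% with log2(FPKM + 0.1). The median log2 fold change of all genes was 0.151 with the voom values against 0.011 by edgeR. The voom values are scaled to library totals without TMM factors. These factors were 0.9684 and 0.8937 at day 0 and 0.9913 and 1.063 at day 1. Leaving out 1 library at a time moved the higher count to 1301 without day 0 replicate 2 and to 1334 without day 2 replicate 1. The lower count was 879 without day 0 replicate 2, 983 without day 2 replicate 1, 943 without day 1 replicate 1 and 919 without day 2 replicate 2. The hedgehog receptors and mediators had 3 genes higher without day 0 replicate 2 and 3 without day 2 replicate 1.

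Which programs followed a day later was asked by comparing day 2 with day 1. Most ventral progenitor genes were higher at this step, after part of them at day 1. Nkx6-1 (chromosome 5, 101658139 to 101664996) rose from 0.661 ± 0.17 to 64.5 ± 8.86 CPM (log2 fold change 6.59 ± 0.25, adjusted p = 1.12e-05). Shh (chromosome 5, 28456815 to 28467256), the floor plate signal itself, rose from 0.638 ± 0.291 to 38.6 ± 17.3 CPM. Ptch1 reached 490.1 ± 34.6 CPM and Gli1, the transcriptional effector and readout of the pathway, rose from 7.57 ± 2.9 to 76.8 ± 0.481 CPM. The counts were 1623 genes higher and 1679 lower at day 2.

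At day 1 the ventral progenitor list had 6 of 14 tested genes higher, 1 lower and 7 not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.064). At day 2 it had 13 of 14 tested genes higher, 0 lower and 1 not called (13 and 0 adjusted over the list alone, camera adjusted p = 2.84e-09, and adjusted p = 0.0832 with an estimated correlation). Hedgehog targets had 8 of 8 tested genes higher, 0 lower and 0 not called (8 and 0 adjusted over the list alone, camera adjusted p = 5.31e-08, and adjusted p = 0.0832 with an estimated correlation). Nkx2-2, Nkx2-9, Nkx6-1 and Foxa2 belong to both this list and the ventral progenitor list, so the results of these lists are not independent. Nkx2-9 rose from 0.474 ± 0.0953 to 12.9 ± 2.59 CPM and Foxa2 from 8.97 ± 0.348 to 83.8 ± 30.2 CPM. Olig2, a motor neuron progenitor factor, rose from 0.673 ± 0.0681 to 32.6 ± 0.76 CPM. Dorsal and intermediate progenitor genes had 6 of 15 tested genes higher, 2 lower and 7 not called (7 and 2 adjusted over the list alone, camera adjusted p = 0.0677). Neural progenitor genes had 14 of 16 tested genes higher, 0 lower and 2 not called (15 and 0 adjusted over the list alone, camera adjusted p = 9.87e-12, and adjusted p = 0.0567 with an estimated correlation), among them Pou3f2, which rose from 1.44 ± 0.311 to 47.1 ± 2.56 CPM. The Notch pathway list had 11 of 15 tested genes higher, 0 lower and 4 not called (12 and 0 adjusted over the list alone, camera adjusted p = 3.35e-07, and adjusted p = 0.0832 with an estimated correlation), and the ligand gene Jag1 rose from 6.28 ± 0.0046 to 52.9 ± 6.86 CPM. The proneural gene Neurod4 rose from 0.195 ± 0.122 to 28.3 ± 3.64 CPM within a neuronal list of 11 of 19 tested genes higher, 3 lower and 5 not called (12 and 3 adjusted over the list alone, camera adjusted p = 0.000342, and adjusted p = 0.0813 with an estimated correlation). Hindbrain regionalization genes had 9 of 13 tested genes higher, 1 lower and 3 not called (10 and 1 adjusted over the list alone, camera adjusted p = 5.4e-06, and adjusted p = 0.0813 with an estimated correlation). Parts of these lists were called at day 1 already, with 7 of 16 neural progenitor genes higher and 2 lower (camera adjusted p = 0.0685). Hindbrain regionalization genes then had 6 of 13 higher and 3 lower (camera adjusted p = 0.26). Neuronal genes had 6 of 19 higher and 4 lower (camera adjusted p = 0.97).

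Retreat from pluripotency went on between these days. Pou5f1 (chromosome 17, 35506018 to 35510772) fell from 82 ± 37.8 to 4.26 ± 0.713 CPM (log2 fold change -4.26 ± 0.40, adjusted p = 0.000256), and the RNA-binding gene L1td1 fell from 232 ± 42.3 to 10.2 ± 0.109 CPM. Naive pluripotency genes had 0 of 15 tested genes higher, 12 lower and 3 not called (0 and 13 adjusted over the list alone), and general pluripotency genes had 0 of 12 tested genes higher, 8 lower and 4 not called (0 and 8 adjusted over the list alone). Cyp26a1 fell back to 24.6 ± 7.64 CPM from 219 ± 22.5, while Crabp1, which codes for an RA-binding protein, rose from 14.2 ± 3.79 to 290.5 ± 67.6 CPM. The RA response list had 6 of 17 tested genes higher, 4 lower and 7 not called (9 and 7 adjusted over the list alone) at this step. Id1 rose again to 28 ± 5.43 CPM and Id3 from 1.69 ± 1.27 to 101 ± 17.9 CPM. The extraembryonic endoderm list had 10 of 18 tested genes higher, 0 lower and 8 not called (12 and 0 adjusted over the list alone, camera adjusted p = 1.67e-05, and adjusted p = 0.314 with an estimated correlation). Fewer genes were called at day 2 when either day 2 library or day 1 replicate 1 was left out, and more were higher without day 1 replicate 2. Each such fit leaves a lone library in a group, so fewer calls need not mean that they rest on the library left out. The day 1 calls also fell without either day 2 library, which that comparison does not hold. The extraembryonic endoderm list had 3 genes higher without day 2 replicate 1, 4 without day 2 replicate 2 and 5 without day 1 replicate 1, and the dorsal and intermediate list had 2, 1 and 1 higher. The RA response list had 2 lower without day 1 replicate 2 and 2 without day 2 replicate 1, and the neuronal list had 1 lower without day 2 replicate 1. With log2(FPKM + 1) without a filter 36% of the day 2 calls were higher, against 49.15% by edgeR.

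Which genes marked the birth of neurons was asked by comparing day 3 with day 2. Nefm (chromosome 14, 68082590 to 68124846), a neurofilament subunit, rose from 5.79 ± 0.377 to 214 ± 65.6 CPM (log2 fold change 5.21 ± 0.26, adjusted p = 0.000113). Dcx (chromosome X, 143855842 to 143933311), which codes for doublecortin of migrating young neurons, rose from 9.83 ± 2.03 to 143 ± 25.6 CPM. Elavl4, a neuronal RNA-binding gene, rose from 22.1 ± 3.1 to 188 ± 10.5 CPM, Stmn2, a microtubule regulator of axons, from 17.6 ± 3.37 to 106 ± 2.64 CPM, and Ebf3 from 6.36 ± 0.672 to 51.7 ± 1.87 CPM. The neuronal differentiation list had 18 of 19 tested genes higher, 0 lower and 1 not called (18 and 0 adjusted over the list alone, camera adjusted p = 7.86e-27), and its call held with an estimated correlation (adjusted p = 0.00801). The motor neuron factor Isl1 rose from 4.08 ± 0.404 to 55.5 ± 9.57 CPM, and Chat, the acetylcholine-synthesizing enzyme, from the edge of the floor at day 2, with 3 counts in each library, to 5.62 ± 3.03 CPM. In total 473 genes were higher and 211 lower at day 3. Without day 3 replicate 1 the counts were 10 and 3, without day 2 replicate 2 they were 18 and 6, and without day 2 replicate 1 they were 54 and 30. Of the calls at day 3, 69.15% were higher by edgeR, 50% with log2(FPKM + 0.1), 82.3% with log2(FPKM + 1) without a filter and 58.9% with a GC offset. The neuronal list had 6 genes higher without day 3 replicate 1 and 7 without day 2 replicate 2. The calls of Nefm, Dcx, Elavl4, Stmn2 and Ebf3 held without any 1 library. Without day 3 replicate 1 the adjusted p was 0.0547 for Isl1 and 0.0551 for Chat. Without day 2 replicate 2 it was 0.0501 and 0.0664 for these genes. With log2(FPKM + 1) without a filter it was 0.0849 for Chat.

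Ventral progenitor genes had 5 of 14 tested genes higher, 0 lower and 9 not called (8 and 0 adjusted over the list alone, camera adjusted p = 7.18e-07, and adjusted p = 0.193 with an estimated correlation). Neural progenitor genes had 5 of 16 tested genes higher, 0 lower and 11 not called (10 and 1 adjusted over the list alone). Gdf3, a pluripotency-linked TGF-beta ligand gene, fell from 6.09 ± 1.51 to 0.545 ± 0.103 CPM. The early hindbrain gene Hoxb1 fell from 12.2 ± 6.59 to 0.533 ± 0.442 CPM and Stra8 from 168 ± 101 to 6.94 ± 4.16 CPM. Without day 3 replicate 1 the adjusted p was 0.0721 for Hoxb1 and 0.0697 for Stra8, and it was 0.073 for Hoxb1 with log2(FPKM + 1) without a filter. The 2-cell-like list, genes of a rare totipotent-like state, had 0 of 11 tested genes higher, 7 lower and 4 not called (0 and 10 adjusted over the list alone, camera adjusted p = 4.77e-09, and adjusted p = 0.193 with an estimated correlation), and whether its Zscan4 and Usp17l copies share reads was not tested, so they are uncertain as single genes. Without day 3 replicate 1, and also without day 2 replicate 2, 0 genes of the ventral, neural progenitor and 2-cell-like lists were called by edgeR, with an unadjusted p under 0.05 for 5, 10, 9 genes without day 3 replicate 1 and 5, 8, 10 without day 2 replicate 2. DESeq2 was not run without single libraries. Without day 2 replicate 1 these lists had 3 higher, 0 higher and 1 lower, and without day 3 replicate 2 the neural progenitor list had 3 higher and 2 lower. The day 3 libraries lay far apart for some patterning genes, with Shh at 196 ± 116 CPM and Pax6, a dorsal and intermediate progenitor gene, at 39.1 ± 37.9 CPM.

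**Figure D2:**
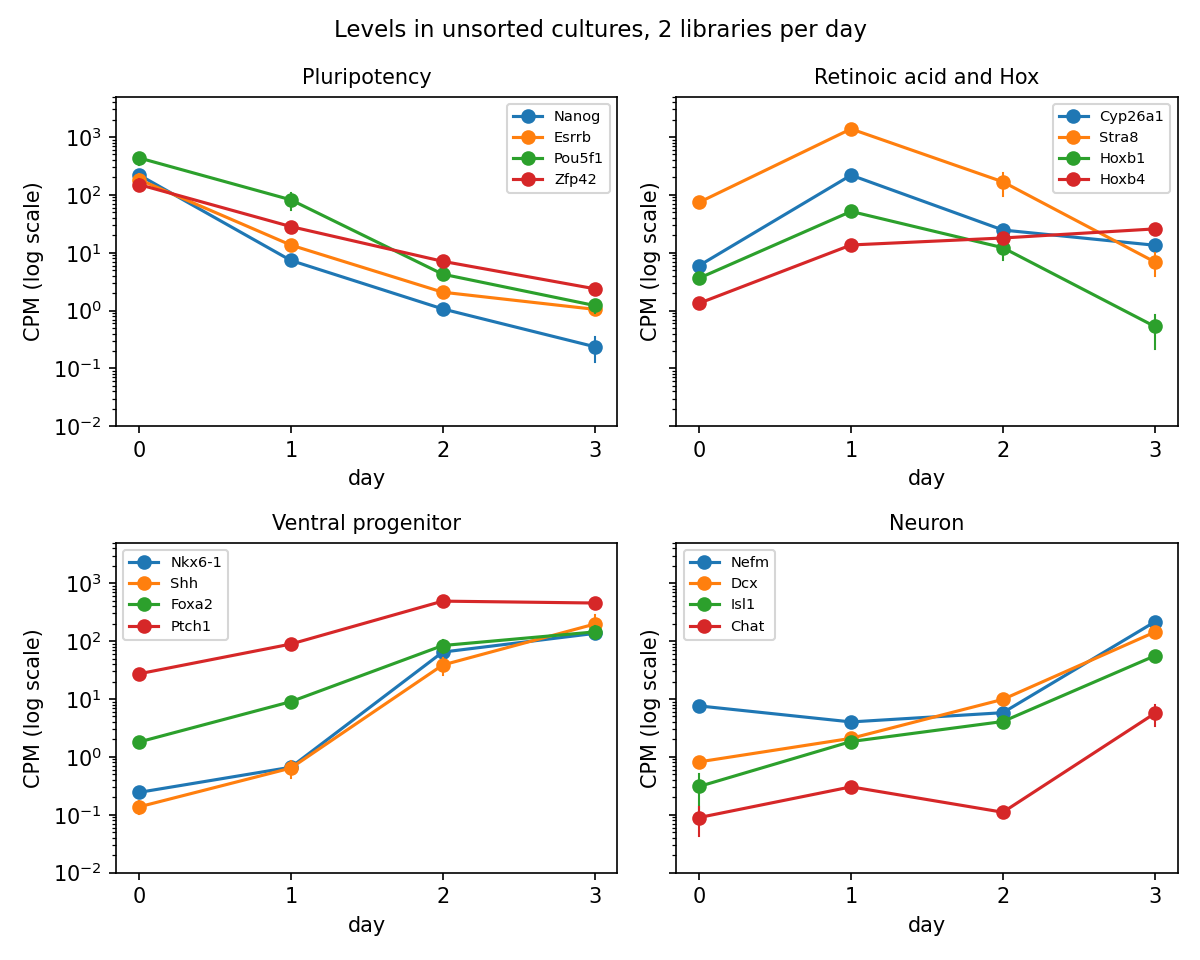
Mean levels in CPM on a log axis are plotted against day for 4 genes each of pluripotency, RA response and Hox, ventral progenitors and neurons. Vertical lines span the 2 libraries of a day. Nanog fell from 221 CPM at day 0 to 0.238 CPM at day 3, and Nefm stood at 214 CPM at day 3.

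The whole interval was measured by comparing day 3 with day 0, with 4641 genes higher and 4422 lower. Nkx6-1 had a log2 fold change of 9.09 ± 0.29, adjusted p = 9.9e-07 and stood at 136 ± 3.77 CPM after 0.243 ± 0.0409. Pou3f2, a neural POU factor, had 7.67 ± 0.32, adjusted p = 1.36e-06, and Nanog had -9.82 ± 0.42, adjusted p = 1.36e-06. Every neural progenitor gene tested was higher, with 16 of 16 tested genes higher, 0 lower and 0 not called (16 and 0 adjusted over the list alone). The ventral progenitor list had 14 of 14 tested genes higher, 0 lower and 0 not called (14 and 0 adjusted over the list alone) and the neuronal list 16 of 19 tested genes higher, 1 lower and 2 not called (16 and 1 adjusted over the list alone). Forebrain and midbrain genes had 3 of 12 tested genes higher, 4 lower and 5 not called (3 and 4 adjusted over the list alone, camera adjusted p = 0.447). Hindbrain regionalization genes had 8 of 13 tested genes higher, 1 lower and 4 not called (8 and 1 adjusted over the list alone), and dorsal and intermediate progenitor genes 4 of 15 tested genes higher, 1 lower and 10 not called (4 and 1 adjusted over the list alone). Among lineages outside the neural tube, mesoderm and definitive endoderm genes had 4 of 15 tested genes higher, 5 lower and 6 not called (5 and 5 adjusted over the list alone), and trophoblast and surface ectoderm genes 5 of 14 tested genes higher, 5 lower and 4 not called (5 and 5 adjusted over the list alone). Neural crest genes had 4 of 8 tested genes higher, 1 lower and 3 not called (4 and 1 adjusted over the list alone) and fibroblast genes 8 of 13 tested genes higher, 3 lower and 2 not called (8 and 3 adjusted over the list alone). Extraembryonic endoderm genes had 9 of 18 tested genes higher, 2 lower and 7 not called (11 and 2 adjusted over the list alone, camera adjusted p = 0.0505). The 2-cell-like list had 0 of 11 tested genes higher, 11 lower and 0 not called (0 and 11 adjusted over the list alone) and the DNA methylation and demethylation list 1 of 10 tested genes higher, 6 lower and 3 not called (1 and 6 adjusted over the list alone). The S phase list had 0 of 13 tested genes higher, 10 lower and 3 not called (0 and 12 adjusted over the list alone, camera adjusted p = 0.000478, and adjusted p = 0.383 with an estimated correlation). The G2 and M phase list had 0 of 15 tested genes higher, 9 lower and 6 not called (1 and 9 adjusted over the list alone, camera adjusted p = 0.0184, and adjusted p = 0.418 with an estimated correlation). Without day 3 replicate 1 these lists had 4 and 3 genes lower. The p53 and apoptosis list had 3 of 13 tested genes higher, 4 lower and 6 not called (3 and 4 adjusted over the list alone), and immediate early and dissociation stress genes had 2 of 14 tested genes higher, 5 lower and 7 not called (2 and 5 adjusted over the list alone). The median log2 fold change of all genes was 0.175 with the deposited voom values and 0.128 with log2(FPKM + 0.1), against 0.016 by edgeR. The voom values carry no TMM factors, which were 0.9684 and 0.8937 at day 0 and 1.056 and 1.017 at day 3. Forebrain and midbrain genes had 1 higher without day 0 replicate 1, 1 without day 0 replicate 2 and 0 by edgeR without day 3 replicate 2, where 5 genes had an unadjusted p under 0.05. Without day 3 replicate 1, 5 fibroblast genes were higher and 1 lower, and the lower count was also 1 without day 0 replicate 2, day 2 replicate 1, day 2 replicate 2 or day 3 replicate 2, each left out alone. Mesoderm and definitive endoderm genes had 3 lower without day 0 replicate 1 and 3 without day 3 replicate 1. Immediate early genes had 3 lower and neural crest genes 2 higher without day 3 replicate 1 and the same numbers without day 3 replicate 2, and trophoblast and surface ectoderm genes 3 higher without day 0 replicate 2 or day 3 replicate 1.

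Whether Hox genes came on in the order of their paralog groups was asked from the day each was higher than day 0. Of 21 Hox genes called higher, 20 were higher at day 1 already and 1, Hoxc8, only from day 2. Spearman's rho between paralog group and day across these genes was 0.298 (permutation p = 0.335, two-sided, 100000 permutations, genes not being independent replicates). With 20 of 21 genes on the same day, daily samples carried almost no order to test. Among 12 Hox genes timed by a level of 1 CPM, rho was -0.486 (permutation p = 0.164). By the edgeR calls rho was -0.347 without day 0 replicate 1, -0.347 without day 0 replicate 2 and -0.0291 without day 1 replicate 2.

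How sorted progenitors differed from the unsorted culture was asked by comparing day 3.5 with day 3. Genes of extraembryonic endoderm, the yolk sac lineage that stem cell cultures can contain, were lower in the sorted libraries. Cubn (chromosome 2, 13276338 to 13491813), which codes for the uptake receptor cubilin of visceral endoderm, fell from 97.1 ± 1.62 to 2.22 ± 0.803 CPM (log2 fold change -5.43 ± 0.22, adjusted p = 6.96e-07). The endoderm regulators Gata6 (chromosome 18, 11052064 to 11085635) and Gata4 fell to 1.66 ± 0.485 and 0.983 ± 0.667 CPM from 17.9 ± 2.92 and 32.8 ± 10.4 CPM. Sox17, another of these regulators, fell from 7.04 ± 2.32 CPM to a mean below the floor of 3 counts per library, with 8 counts over the 3 sorted libraries. The laminin gene Lamb1 fell from 886 ± 282 to 103 ± 16.1 CPM. Prom1 (chromosome 5, 43993620 to 44102032), which codes for the sorted protein, was at 299.7 ± 29.5 CPM against 238 ± 34 in the unsorted culture and was not called (log2 fold change 0.33 ± 0.15, adjusted p = 0.315). In all 74 genes were higher and 499 lower of 17006 tested.

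The extraembryonic endoderm list had 0 of 18 tested genes higher, 16 lower and 2 not called (0 and 16 adjusted over the list alone, camera adjusted p = 4.48e-30), and its call held with an estimated correlation (adjusted p = 0.0447). General pluripotency genes had 0 of 12 tested genes higher, 7 lower and 5 not called (0 and 9 adjusted over the list alone, camera adjusted p = 4.08e-08, and adjusted p = 0.0587 with an estimated correlation), and L1td1 fell from 7.57 ± 0.772 to 0.355 ± 0.17 CPM. Trophoblast and surface ectoderm genes had 0 of 14 tested genes higher, 6 lower and 8 not called (0 and 10 adjusted over the list alone, camera adjusted p = 2.79e-11, and adjusted p = 0.153 with an estimated correlation). Their epithelial members Epcam and Cdh1, which code for cell adhesion proteins, fell to 3.86 ± 0.964 and 61 ± 2.81 CPM from 20.2 ± 5.04 and 185 ± 19.4. Naive pluripotency genes had 0 of 15 tested genes higher, 5 lower and 10 not called (0 and 8 adjusted over the list alone, camera adjusted p = 0.000231, and adjusted p = 0.293 with an estimated correlation). The lower count was 3 without day 3 replicate 1 and 3 without day 3.5 replicate 2. The 2-cell-like list had 0 of 11 tested genes higher, 3 lower and 8 not called (0 and 6 adjusted over the list alone, camera adjusted p = 0.000519, and adjusted p = 0.293 with an estimated correlation). Its median log2 fold change was -3.41 against -2.66 for extraembryonic endoderm. Its lower count was 1 without day 3 replicate 2, 1 without day 3.5 replicate 1 and 1 without day 3.5 replicate 3. Fibroblast genes had 0 of 13 tested genes higher, 2 lower and 11 not called (0 and 6 adjusted over the list alone, camera adjusted p = 0.000198, and adjusted p = 0.199 with an estimated correlation). There was 1 lower without day 2 replicate 1, day 2 replicate 2, day 3 replicate 1, day 3.5 replicate 1 or day 3.5 replicate 2, each left out alone. Cyp26a1 fell from 13.5 ± 4.14 to 0.388 ± 0.183 CPM. Fabp7 (chromosome 10, 57784881 to 57788450), a radial glia gene, rose from 23.9 ± 9.85 to 162 ± 62.9 CPM (log2 fold change 2.76 ± 0.36, adjusted p = 0.00147), and the Wnt ligand gene Wnt5a from 14.3 ± 2.98 to 40.5 ± 3.82 CPM. Fabp7 belongs to the neural progenitor list, which had 1 of 16 tested genes higher, 0 lower and 15 not called. Adjusted over the list alone 3 were higher and 0 lower (camera adjusted p = 0.00109, and adjusted p = 0.136 with an estimated correlation). The median log2 fold change of this list was 0.192.

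The motor neuron gene Isl1 was at 74.8 ± 20.5 CPM in the sorted libraries and was not called against 55.5 ± 9.57 CPM at day 3. By edgeR the neuronal differentiation list had 0 of 19 tested genes higher, 0 lower and 19 not called (0 and 0 adjusted over the list alone, camera adjusted p = 0.00809, and adjusted p = 0.513 with an estimated correlation). Ventral progenitor genes had 0 of 14 tested genes higher, 0 lower and 14 not called (0 and 0 adjusted over the list alone), hedgehog targets 0 of 8 tested genes higher, 0 lower and 8 not called (0 and 0 adjusted over the list alone) and immediate early and dissociation stress genes 0 of 15 tested genes higher, 0 lower and 15 not called (0 and 0 adjusted over the list alone). Beside these 0 calls by edgeR, the p-value before adjustment was under 0.05 for 4 neuronal, 3 ventral, 2 hedgehog target and 4 immediate early genes, and DESeq2 called 1, 0, 0 and 1 of them. The sorted libraries differ from all others in sort, in the project code of their descriptions and, by their cell status, in day. These cannot be told apart, and no value within a project code can be had. The higher count was 32 without day 2 replicate 1, 35 without day 2 replicate 2, 11 without day 3 replicate 1, 34 without day 3 replicate 2, 11 without day 3.5 replicate 1 and 12 without day 3.5 replicate 2. The lower count was 173 without day 3 replicate 1, 219 without day 3.5 replicate 1 and 234 without day 3.5 replicate 2. General pluripotency genes had 3 lower without day 3 replicate 1, 4 without day 3 replicate 2, 4 without day 3.5 replicate 1 and 3 without day 3.5 replicate 2, and trophoblast and surface ectoderm genes had 3 lower without day 3 replicate 1. Of the calls, 12.91% were higher by edgeR, 22.5% by DESeq2 and 7.32% with log2(FPKM + 0.1). This share was 7.14% without day 2 replicate 1, 8.08% without day 2 replicate 2, 5.98% without day 3 replicate 1, 7.56% without day 3 replicate 2, 4.78% without day 3.5 replicate 1 and 4.88% without day 3.5 replicate 2. With settings added after seeing the data it was 24.9% with a GC offset and 26.4% without the 3 libraries of highest GC trend.

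**Figure D3:**
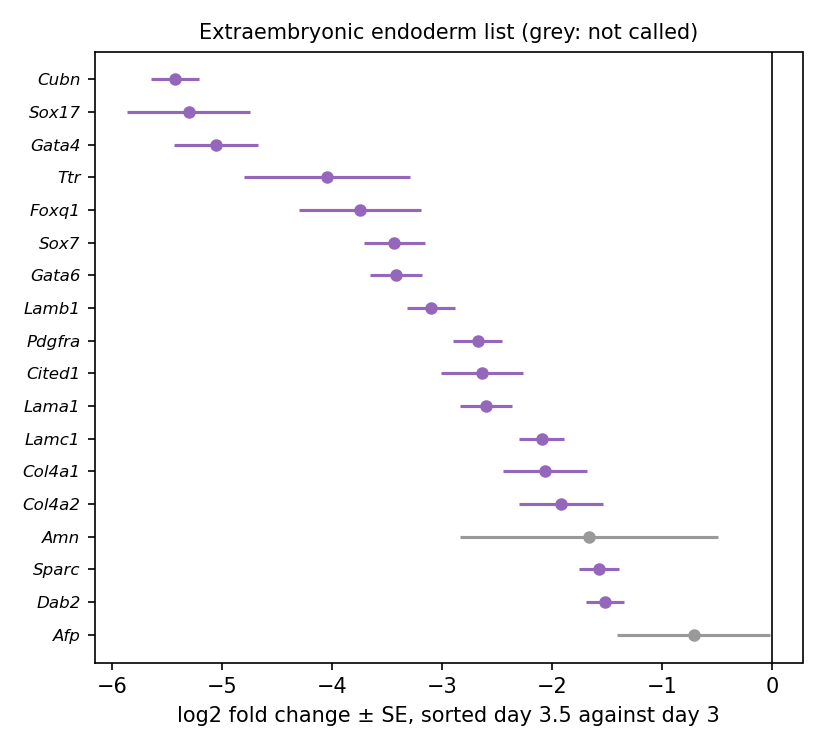
Log2 fold changes of the extraembryonic endoderm genes in the 3 sorted day 3.5 libraries against the 2 day 3 libraries are drawn with their SE as horizontal bars. Genes called lower are purple and the others grey, and Cubn lies at -5.43 ± 0.22.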

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

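The GC offset and the fits without 3 libraries of lowest or highest GC trend were chosen after seeing the data, and the other alternatives before. Of 1276 repeats of the 59 named gene results, 1267 kept direction and side of the threshold, 9 lost a call and 0 turned direction. Named genes outside the fixed panel were picked from these data for large changes or small adjusted p, so their calls were likely to hold. Of all calls at day 3 against day 2, 98.8% were kept by DESeq2, 55.4% with the replicate block and 8.63% with log2(FPKM + 0.1). Calls of d3 against d0 ranged from 3719 to 5418 higher and 2836 to 5367 lower over the settings other than leaving out a library, and any change over days 0 to 3 from 7077 to 11221 genes. The lower count moved by more than 1.5 times only at 2836, with a minimum log2 fold change of 1, and that setting also gave 797 lower at day 1, by its construction.

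The GC offset gave 3174 higher and 2817 lower at day 1, 2749 lower at day 2, 1420 and 990 at day 3 against day 2, and 296 and 893 at day 3.5. Without the 3 libraries of lowest GC trend there were 893 lower at day 1, and 1215 and 735 at day 3 against day 2. Without the 3 of highest GC trend there were 3697 and 2869 at day 2, 1302 and 779 at day 3 against day 2, and 327 and 911 at day 3.5. No filter on low counts gave 991 and 617 at day 3 against day 2 and 137 and 856 at day 3.5. DESeq2 gave 951 and 523, and 220 and 758. With other libraries in the fit, day 3 against day 2 gave 962 and 469. FPKM with pseudocount 1 gave 760 lower at day 1, 927 higher at day 2, 163 and 53 at day 3 against day 2, and 29 and 236 at day 3.5. With pseudocount 0.1 these were 690, 886, 44 and 44, and 26 and 329. Without the FPKM filter they were 795, 776, 209 and 45, and 31 and 232. The deposited voom values gave 293 higher at day 3 against day 2. The cause was not tested in any of these.

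Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 1301 to 1715 higher and 879 to 1303 lower at day 1, 593 to 2493 and 408 to 1875 at day 2, 10 to 650 and 3 to 306 at day 3 against day 2, 3465 to 5020 and 2964 to 4649 at day 3 against day 0, and 11 to 84 and 173 to 588 at day 3.5. Any change over days 0 to 3 ranged from 6655 to 10071 genes.

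Of 145 list tests, 76 were called with the preset correlation and 2 with an estimated one, 65 with fry and 77 with other libraries in the fit. Both the preset camera test and fry called 54, in the same direction. The lost calls cannot be laid to correlation between genes alone. For FGF/ERK targets at day 1 the estimate was -0.0258, below the preset 0.01, and the unadjusted camera p still went from 2.49e-07 to 0.00555. The Hox order turned from 0.298 to -0.486 by the 1 CPM rule, and ranged from -0.347 to 0.301 without 1 library. Without day 2 replicate 2 all Hox genes called higher were so from day 1 and no rho could be had.

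The labels do not say whether the replicate numbers pair libraries across days. The deviations below cannot settle it, since they differ in sign between days and in part follow GC content. Deviations of same-numbered libraries correlated at -0.836 for days 0 and 1, -0.375 for days 0 and 2, 0.364 for days 0 and 3, 0.468 for days 1 and 2, -0.418 for days 1 and 3 and 0.0407 for days 2 and 3. With the replicate block there were 977 lower at day 1, 282 and 111 at day 3 against day 2, and 34 and 232 at day 3.5. The block gave 1498 higher at day 1, 1190 and 1226 at day 2, 4294 and 4013 at day 3 against day 0, 7709 with any change and 84 list calls, within 1.5 times, and no named gene changed its call.

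In the sorted comparison totals of 13173674 to 17113430 stood against 30115258 and 30264387 at day 3. With day 3 thinned to the mean total of day 3.5 edgeR called 66 higher and 461 lower, against 74 and 499 at full depth.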

Other observations

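The lists of germ cell and of neuron subtype genes below, the question of sort against time and the test of stage with the GC trend kept, were chosen after the results were seen. The GC offset was added after the GC trend was seen, and both patterns weighed were picked from the results. The other tests had their thresholds written before they were run, that of length with the GC trend kept only after its value without the trend was known, and the median of the endoderm list was already known when it was set against random lists.

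Genes of germ cells and meiosis were in part higher at day 1 and mostly lower from day 2. Of 21 tested genes of a list of 24, 6 were higher and 1 lower at day 1, and 15 were lower at day 2. Without day 0 replicate 1 the day 1 counts were 2 and 3, without day 0 replicate 2 they were 5 and 0, without day 1 replicate 1 they were 2 and 1, and without day 1 replicate 2 they were 3 and 0. Without day 2 replicate 1, 7 were lower at day 2. Stra8, the RA-induced gatekeeper of meiosis, went from 74.3 ± 23 CPM at day 0 to 1377 ± 84.4 at day 1 and 6.94 ± 4.16 at day 3. The meiotic cohesin gene Rec8 went from 15.1 ± 4.86 to 148 ± 52.5 CPM at day 1, while the germ cell RNA-binding gene Dazl, at 47.3 ± 27.9 CPM at day 0, was not called at day 1 (101 ± 30.6 CPM, adjusted p = 0.289) and was at 11.4 ± 6.91 CPM at day 2. Sycp3 and Hormad1, genes of the meiotic chromosome axis, were not called at day 1 (adjusted p = 0.29 for Sycp3 and 0.197 for Hormad1), with Sycp3 at 22 ± 7.14, 13.5 ± 3.54 and 0.717 ± 0.0147 CPM and Hormad1 at 19.9 ± 8.83, 10.5 ± 2.96 and 0.695 ± 0.457 CPM at days 0, 1 and 2.

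Most tested genes of lists for motor and serotonergic neurons were higher at day 3 than at day 0. These were 7 of 8 tested genes of a list written for visceral motor neurons, 4 of 6 serotonergic genes, with 1 lower, and 3 of 3 genes of a list written for spinal somatic motor neurons. The visceral list also holds Isl1, Lhx4 and the cholinergic genes Chat, Slc18a3 and Slc5a7, which other motor neurons express too, so these counts do not tell motor neuron subtypes apart. Levels at day 3 were 55.5 ± 9.57 CPM for Isl1, 51.7 ± 19.2 for Tbx20, 28.1 ± 5.43 for Lhx4, 3.35 ± 1.14 for Mnx1, 2.39 ± 2.04 for Lhx3 and 1.36 ± 0.0997 for Isl2. Tph2, the serotonin-synthesizing enzyme, was at 0.465 ± 0.169 CPM. Between days 2 and 3, 6 genes of the visceral list were higher, but edgeR called 0 without day 2 replicate 2 and 0 without day 3 replicate 1, where 6 genes each had an unadjusted p under 0.05 and DESeq2 was not run. The lists were not tested against each other.

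Replicate libraries of day 0 and of day 1 differed along the GC content of transcripts, in opposite senses by replicate number. Across 9761 genes, which are not independent replicates, the differences of both days correlated at -0.836, and a GC trend accounted for 53.9% of the variance of the difference at day 0, 64.7% at day 1, 19.8% at day 2 and 15.6% at day 3. Removing the trend left r = -0.609, which argues against the GC content of the longest transcript as the whole cause. For what the trend left at day 1, transcript length (Spearman rho -0.0555) and a difference in stage of differentiation (r = 0.142 with the day 2 against day 1 change) were argued against, both values being under the bounds written beforehand. For the part along GC content both stay open, with the trend kept, at rho 0.165 for day 0 and -0.209 for day 1 and r = 0.424 for stage.

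Extraembryonic endoderm genes were lower in the sorted day 3.5 libraries, as were some pluripotency, 2-cell-like, fibroblast and trophoblast and surface ectoderm genes, and a candidate explanation is that unsorted cultures carried endoderm-like cells that the Prominin-1 sort removed. Cubn was at 175 ± 9.86, 168 ± 29.3, 157 ± 4.94 and 97.1 ± 1.62 CPM at days 0 to 3, the most abundant list genes at day 3 were Col4a1 at 1579 ± 746, Lama1 at 1290 ± 484 and Sparc at 1157 ± 355 CPM, and of the 20 list genes 13 reached 5 CPM at day 0, 15 at day 3 and 8 at day 3.5, while 2, Sox17 and Pdgfra, are in another list. Depth was argued against, since 16 of 18 genes were called lower with day 3 thinned to the mean total of the day 3.5 libraries, and so was GC content, with 16 lower under the GC offset. Random lists matched on expression, GC content and length did not fall as this list did. Its median of -2.66 lay at percentile 0.01, the smallest that 10000 such lists can give, against a 95% range of -0.27 to 0.1. The list was picked from the results with its median known, and the random genes were drawn singly. The comparison therefore cannot decide on a batch effect that moves related genes together. Loss by the sort, a change between days 3 and 3.5 and the project code cannot be told apart. With days taken from the cell status, 0 of the 11 libraries are sorted at day 3 or unsorted at day 3.5. By the label that says 3 days the sorted libraries would be of day 3, and sort and project code would still coincide.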
